A study of Homo sapiens with 2 samples.

How the data were processed

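Gene expression was measured in 2 samples of K562, an established human leukaemia cell line that carries the BCR-ABL1 fusion kinase. Both cultures received imatinib, an inhibitor of that kinase, at 2 µM for 6 h, per the labels' protocols. The first had been grown with erythropoietin (EPO), the cytokine that drives red cell formation, and the second, whose label names no EPO, is taken as grown without it from the growth protocol in the labels. Total RNA was isolated with a column kit that also retains small RNAs and was hybridised to 1 whole-transcript Affymetrix Gene ST array per sample, per the labels' protocols. The design therefore has 1 array in each of 2 groups and no replicates. Untreated K562 cells were not analysed here.

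The deposited log2 values form a table of 28869 probes by 2 arrays. The background correction, the summarisation, the normalization, the software and the base of the logarithm are not given in the sources used here. The values are read as log2, which could not be tested. The values themselves show that the authors centred each probe on a baseline. The column medians were -0.0089 with EPO and 0.052 without EPO, and the columns ran from -1.84 to 0.74 and from -1.90 to 3.35. In 631 probes (2.19%) the values of the arrays were equal in size and opposite in sign within 1e-05, and only 23 and 15 probes stood at exactly 0. A median over an even number of at least 4 arrays, with these 2 in the middle, gives such values. Which other arrays entered the baseline is unknown, and they were not analysed here. A value is thus a deviation from an unknown level and says nothing about how abundant a transcript was. The difference between the arrays cancels the baseline, and the comparisons of the 2 arrays rest on it, except where residuals from a trend are named.

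Probes were named through the platform annotation: 19310 probes carried exactly 1 gene symbol, 1752 carried several and 7807 were not listed. Of the 19310, 19279 were matched by Entrez ID to a RefSeq gene table (GRCh38.p14), from which only the symbol and the gene type were taken. Probes with several genes or none entered no gene comparison. Probes of a gene were averaged, which gave 18377 genes, 685 of them with several probes. The median gap between the highest and lowest probe of such a gene was 0.18, and its 95th percentile was 1.16, on the log2 scale of the difference.

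The result for a gene is the log2 value with EPO minus the log2 value without EPO. With 1 array per group there is no replicate error, no test and no p-value, and the number of arrays limits the precision. A gene was called higher or lower by a fixed rule of size, a difference of at least 2-fold (1 on the log2 scale). The 28 gene lists, the rule for named genes and most alternative settings were written before the data were examined. A list's median difference was placed among the medians of 10000 random lists of the same size and was said to stand apart when outside the central 95%. This describes these 2 arrays only. About 1.4 of 28 lists of genes drawn at random would stand apart. The genes of a fixed list were not drawn at random, so 1.4 is no chance rate for them. Of 593 distinct genes in the lists, 538 were measured, and 34 genes stood in more than 1 list.

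Several planned steps need expression levels and were not possible on centred values. These were the filter on dim genes, the matching of random lists on mean expression, the intensity-dependent lowess, the quantile normalization and the choice of the brightest probe. All genes were therefore counted, and random lists were drawn from all genes. After the data had been seen, a pair of reference classes was defined by symbol. The first holds 567 genes with symbols of cellular machinery, such as the proteasome, mitochondrial ribosome, respiratory chain, spliceosome, RNA polymerase II and nuclear pore. It was not checked for members restricted to some tissues. The second holds 479 genes of silent families, which are olfactory, taste and vomeronasal receptors, keratin-associated proteins and beta-defensins. Random lists were drawn from each class as well, and the median of each class was subtracted as another scaling. Comparisons with machinery lists by the mean, and without list members of that class, were added then too.

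The genes named are EPOR, JAK2, STAT5A, STAT5B, ABL1 and BCR, a fixed set of known targets, the 12 largest differences in each direction and up to 3 members with the largest differences in each list. Small RNAs, antigen receptor segments and unnamed loci stayed out of the 12. Genes named beyond this rule were chosen after their values were seen and are marked so. Alternatives tried were other fold thresholds, other scalings, other rules for probes, the mean in place of the median, lists without shared genes and other backgrounds for the random lists. Calculations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3. The list percentile was tested on simulated lists drawn at random from the 18377 gene differences. Of lists of 20 genes, 3.5% with no shift stood apart, as did 23.2% shifted by 0.25, 97% shifted by 0.5 and 100% shifted by 1. The first rate follows from the random draw, and no rate covers lists whose genes move together.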

Results

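The deposited table holds whole-transcript array values of imatinib-treated K562 cells, with 1 array of cells grown with EPO and 1 array of cells grown without it. The pair compares gene expression with and without EPO in leukaemia cells whose BCR-ABL1 kinase is inhibited. All differences are log2 values with EPO minus without EPO, from 1 array each, so no difference has a replicate check. The base of the logarithm is not given in the sources used here, and every fold rests on reading it as 2.

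Across the 18377 genes, 1138 (6.19%) were at least 2-fold higher with EPO and 165 (0.898%) were at least 2-fold lower. The median difference of all genes was -0.047. The split depended on the scaling between the arrays: with the median difference of cellular machinery genes (0.46) subtracted, 134 genes were higher and 1085 lower, and a gene needed a difference of 1.46 to stay 2-fold higher. With the median of silent gene families (-0.33) subtracted, 2804 were higher and 101 lower. Differences below are as deposited. The arrays did not deviate from the authors' baseline to the same extent. The standard deviation across probes was 0.134 with EPO and 0.431 without EPO. With EPO, no gene lay 1 or more above the baseline and 6 lay 1 or more below it. Without EPO, 108 genes lay 1 or more above it and 612 lay 1 or more below it.

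**Figure D1:**
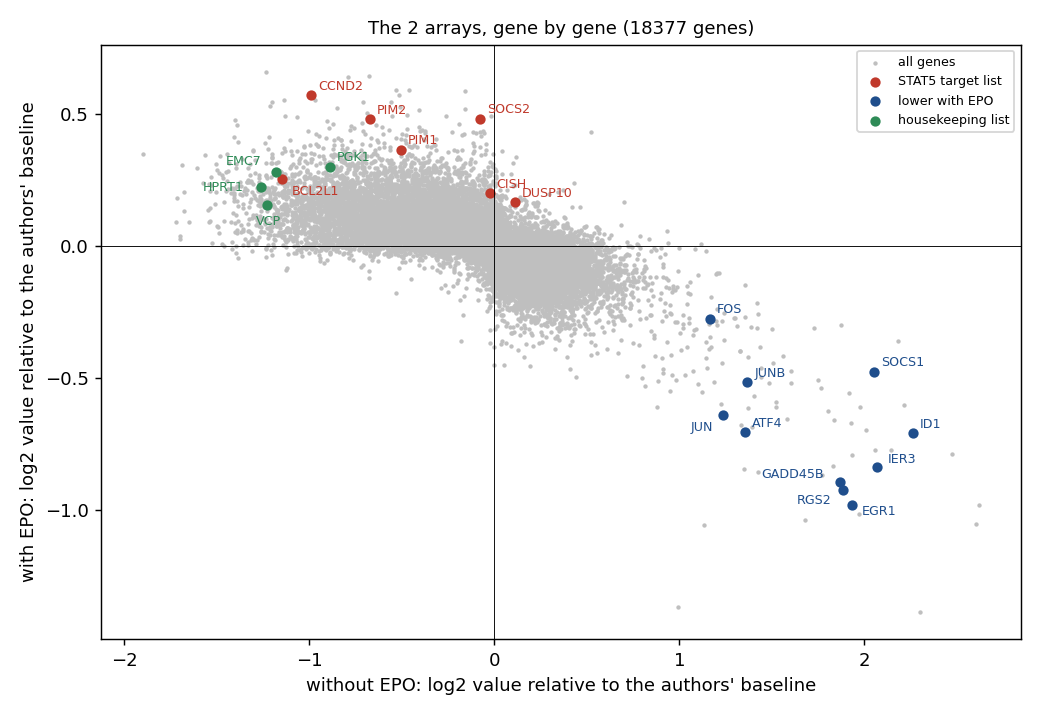
Each grey point is 1 of 18377 genes, with its log2 value relative to the authors' baseline on the array without EPO (x axis) and with EPO (y axis), and coloured points are named genes. The spread is far wider along the x axis, EGR1 and ID1 lie at the lower right, and SOCS2, CCND2 and PIM2 lie along the upper edge of the cloud.

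The differences followed the class of gene. Cellular machinery genes had a median difference of 0.46, and 76 of 567 were at least 2-fold higher with EPO against 2 lower. Proteasome subunits (47 genes) had a median of 0.76, nucleoporins (23 genes) 0.72, translation initiation factors (44 genes) 0.57 and mitochondrial ribosomal proteins (74 genes) 0.41, and only the last of these 4 turned negative with the machinery median subtracted. The fixed list of housekeeping genes, used as references because most cells express them evenly, had a median of 0.64, and 7 of its 23 measured members were at least 2-fold higher with EPO. Among them were HPRT1, an enzyme of purine salvage, at 1.49 (2.80-fold), the membrane protein complex subunit EMC7 at 1.46 and the ATPase VCP at 1.38. GAPDH and ACTB, named after their values were seen, stood at 0.12 and 0.34. Of the 23, 5 also belong to the machinery class. In contrast, the silent families had a median of -0.33, and 91.6% of their 479 genes lay below 0. Collagens (44 genes) had a median of -0.37, which stayed negative with either class median subtracted. Cytosolic ribosomal proteins, which are among the most abundant transcripts of any cell, had a median of 0.022 (0.069 with the median of all genes subtracted) and a mean of 0.084, with 0 of 22 past 2-fold. The largest differences in that list were 0.87 for RPS23, 0.85 for RPL32 and 0.53 for RPL23.

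**Figure D2:**
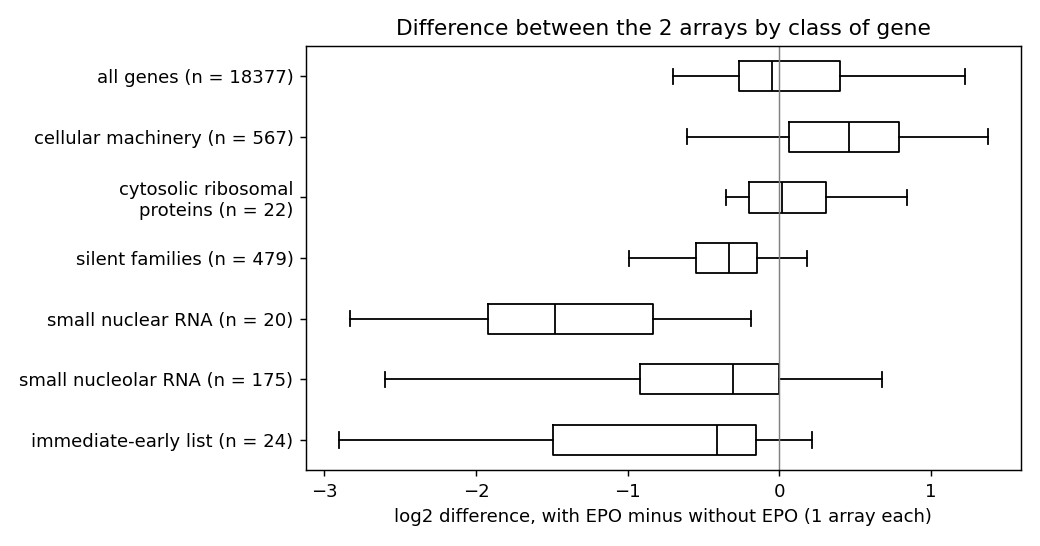
Boxes show the median and the interquartile range of log2 differences (x axis, with EPO minus without EPO) in 7 classes of gene, with whiskers over the central 95%. Machinery genes are centred at 0.46, silent families at -0.33 and small nuclear RNAs at -1.48.

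Genes of the EPO receptor pathway and of the imatinib target were within 2-fold. EPOR, the EPO receptor, stood at 0.31, its kinase JAK2 at 0.39, and the transcription factors STAT5A and STAT5B at 0.21 and 0.35. ABL1 and BCR, the partners of the fusion, stood at 0.65 and 0.022. All 6 lay inside the central 95% of the machinery genes, from -0.62 to 1.38.

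The fixed list of STAT5 target genes split in both directions. Of 20 measured members, 3 were at least 2-fold higher with EPO and 3 at least 2-fold lower, and the list's median was -0.0057 (0.041 with the median of all genes subtracted), at percentile 64.4 of random lists of all genes and 0.12 of random machinery lists. Its mean was -0.12, and its median without genes shared between lists -0.15. The higher genes were CCND2, the cyclin D2 gene, at 1.56 (2.95-fold), BCL2L1, which encodes the survival protein BCL-XL, at 1.40 (2.64-fold) and the kinase PIM2 at 1.15 (2.22-fold). The kinase PIM1 stood at 0.87, and the feedback inhibitors SOCS2 and CISH at 0.56 and 0.22. The lower genes were ID1, an inhibitor of differentiation factors, at -2.97 (7.84-fold lower), the cytokine signalling inhibitor SOCS1 at -2.53 (5.76-fold lower) and GADD45G, named after its value was seen, at -1.21. With the machinery median subtracted, CCND2 stayed past 2-fold, while BCL2L1 and PIM2 did not. CCND2 and BCL2L1 lay at percentiles 98.4 and 98.2 of the machinery genes, and ID1 and SOCS1 lay below every machinery gene and every gene of the silent families.

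The list with the lowest median joins immediate-early genes, which are transcribed within minutes of signalling, with ERK feedback genes. Of 24 measured members, 8 were at least 2-fold lower with EPO and 0 were higher, with a median of -0.41 below all 10000 random lists of all genes. EGR1 stood at -2.92 (7.54-fold lower), IER3 at -2.91 (7.50-fold lower) and JUNB at -1.88 (3.69-fold lower). The other lower members, named after their values were seen, were JUN, FOSB, IER2, IER5 and FOS, between -1.88 and -1.44. The list's median lay inside random silent lists, at percentile 17.0, whereas its mean, -0.82, lay below their central 95% of means (-0.49 to -0.23). The ERK phosphatase DUSP6 stood at -0.10 and MYC, the growth-promoting transcription factor, at 0.067.

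Of the 12 most strongly lower genes under the naming rule, 7 were protein-coding. Besides ID1, EGR1, IER3 and SOCS1 these were RGS2, a regulator of G-protein signalling, at -2.81 (7.01-fold lower), the stress gene GADD45B at -2.76 (6.79-fold lower) and the histone H2AC4 at -2.50. The transcribed pseudogene ROCK1P1 stood at -3.65 (12.6-fold lower), the readthrough transcript SEPT5-GP1BB at -3.60, the non-coding FAM230B at -3.26, the small nuclear RNA RNVU1-4, which the symbol rule did not exclude, at -2.83 and the pseudogene REXO1L1P at -2.59. Members of such families share near-identical sequence, so their identity is uncertain. Of the 165 lower genes, 60 carried symbols of small RNAs, receptor segments or unnamed loci, against 7 of the 1138 higher genes. All 20 small nuclear RNAs lay below 0, with a median of -1.48 that stayed negative with either class median subtracted, and 14 were at least 2-fold lower. Of 175 small nucleolar RNAs, 37 were at least 2-fold lower and 2 higher.

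The 12 most strongly higher genes were UGCG, which makes glucosylceramide, at 2.25 (4.75-fold), FBXO4 at 1.99, the chaperone DNAJA2 at 1.91, ZNF845 at 1.90, the replication licensing factor CDC6 at 1.89 (3.72-fold), ANAPC16, ZNF267, PM20D2, TBPL1, RMND5A, EFCAB10 and CCP110. The last 7 lay between 1.81 and 1.89. Each of the 12 lay at percentile 99.8 or above of the machinery genes.

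**Figure D3:**
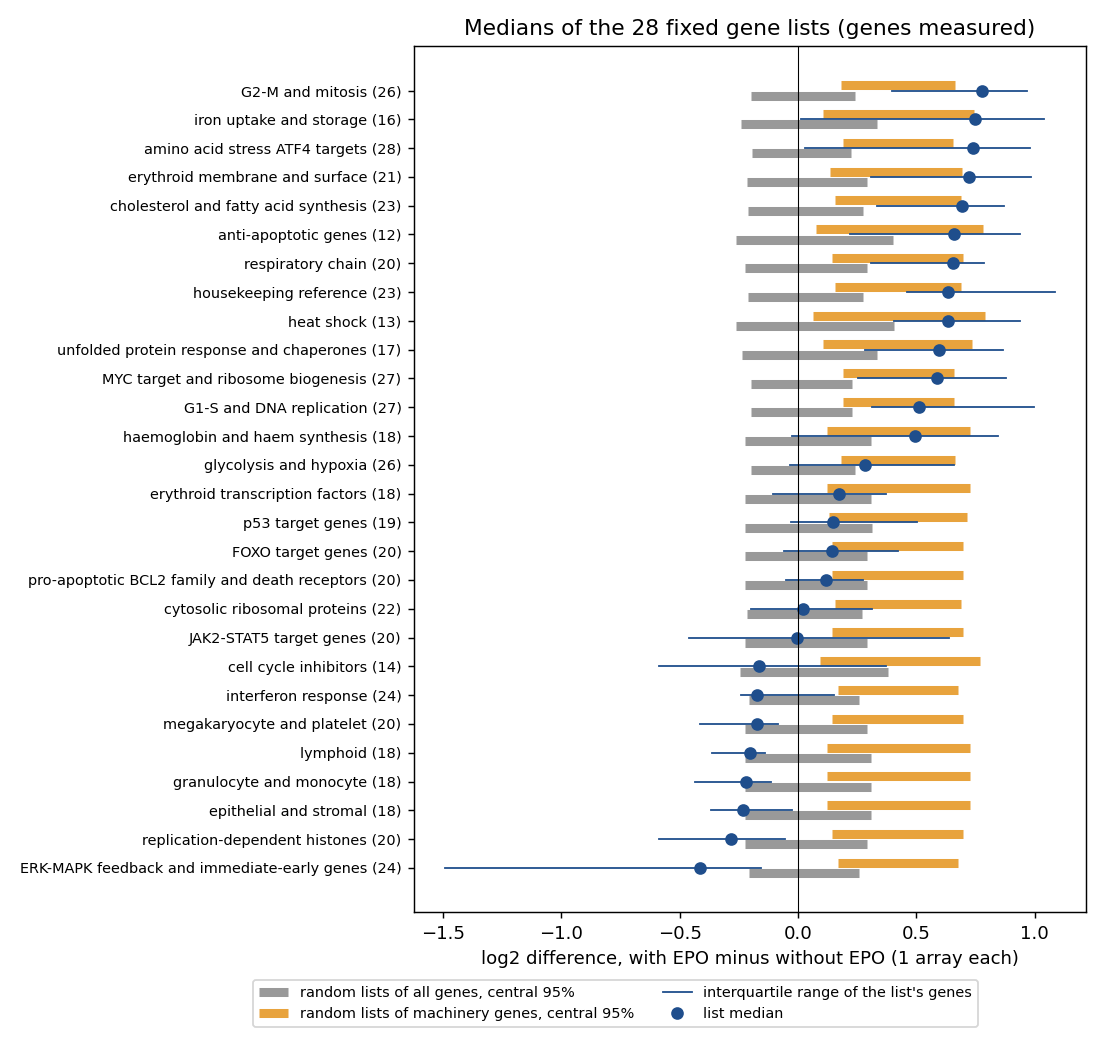
Points are the median log2 differences (x axis, with EPO minus without EPO) of the 28 fixed lists, thin lines the interquartile range of their genes, and bars the central 95% of medians of random lists of the same size from all genes (grey) and from machinery genes (orange). Of the 14 lists above the grey bar, 9 lie within the orange bar, and the immediate-early list lies lowest, at -0.41.

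Of the 28 lists, 14 stood above random lists of all genes and 3 below, against 1.4 in all for lists of genes drawn at random. Of the 14, 5 also stood above random machinery lists: mitosis, iron uptake, ATF4 targets, erythroid surface genes and sterol synthesis. The other 9 of the 14 lay inside the machinery range, among them the housekeeping list at percentile 93.5 and the respiratory chain at 94.9, although 17 of the 20 respiratory chain genes belong to the machinery class. With the mean in place of the median, mitosis and sterol synthesis were the 2 of the 5 that stayed above machinery lists, and the G1-S, heat shock and housekeeping lists stood above them too. With list members of the machinery class left out, the housekeeping list also stood above them, at percentile 99.5. Another 12 of the 28 lay below random machinery lists. These were STAT5 targets, immediate-early genes, FOXO targets, pro-apoptotic genes, cell cycle inhibitors, cytosolic ribosomal proteins, histones, interferon genes, and the megakaryocyte, granulocyte, lymphoid and epithelial lists. Of the 17 lists that stood apart from all genes, the glycolysis list turned negative (-0.18) with the machinery median subtracted, and the epithelial (0.099) and histone (0.050) lists turned positive with the silent median subtracted.

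Of the 4 lists of red cell genes, 3 stood above random lists of all genes. The erythroid membrane and surface list had a median of 0.72 (percentile 98.3 of machinery lists, but 90.3 by the mean), with 5 of 21 members at least 2-fold higher and 0 lower. The membrane transporter XK stood at 1.25, SLC4A1, the band 3 anion exchanger, at 1.19 and RHAG, the Rh-associated glycoprotein, at 1.12. Iron uptake and storage had a median of 0.75 (percentile 97.6 of machinery lists, but 93.2 by the mean), with 6 of 16 higher, led by the iron reductase CYBRD1 at 1.65, the metal transporter SLC39A8 at 1.33 and the iron regulator ACO1 at 1.10. Haemoglobin and haem synthesis had a median of 0.49, inside the machinery range, with 3 of 18 higher: the mitochondrial transporter ABCB10 at 1.37 and the haem enzymes CPOX at 1.29 and FECH at 1.15. The globin genes of that list, named after their values were seen, were within 2-fold, with HBB at -0.00076, HBD at -0.067, HBE1 at 0.11, HBZ at -0.040, HBM at -0.29 and HBQ1 at -0.43. The probes shared by HBG1 and HBG2, the fetal globins, differed by 0.00089 and 0.00074 between the arrays. Erythroid transcription factors had a median of 0.17, inside the range of all genes, with IKZF1 at 1.10, NFE2L2 at 1.00 and FOXO3 at -0.89.

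Some cell division genes were higher with EPO. The mitosis list had a median of 0.77 (percentile 99.7 of machinery lists), with 5 of 26 at least 2-fold higher and 0 lower. CDK1, the mitotic kinase, stood at 1.55, the spindle motor KIF11 at 1.40 and cyclin B2 (CCNB2) at 1.23. G1-S and replication genes had a median of 0.51 (percentile 71.7 of machinery lists, but 98.6 by the mean), with 7 of 27 higher, including CDC6, CCND2 and the helicase subunit MCM6 at 1.55. Cell cycle inhibitors had a median of -0.16, or -0.28 without shared genes, inside the range of all genes, with 2 of 14 lower, BTG1 at -1.49 and CDKN1C at -1.07, and CDKN1B at 0.82. The replication-dependent histones had a median of -0.28, below random lists of all genes and inside the range of random silent lists (mean -0.50), with 4 of 20 lower, including H4C2 at -2.08 and H3C1 at -1.99. MYC target and ribosome biogenesis genes had a median of 0.59 (percentile 90.2 of machinery lists), with WDR12 at 1.56, DDX21 at 1.54 and NOLC1 at 1.08.

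Survival and stress genes were also split by list. Anti-apoptotic genes had a median of 0.66 (percentile 90.3 of machinery lists), or 0.43 with the probe of smallest difference, with BCL2L1, PIM2 and BIRC2 (1.07) the 3 of 12 that were at least 2-fold higher. Pro-apoptotic genes had a median of 0.12, or 0.20 without shared genes, with 1 of 20 higher, CASP9 at 1.03, while BNIP3L stood at 0.76 and BID at 0.64. BCL2L11, which encodes the pro-apoptotic protein BIM, stood at 0.22. ATF4 targets had a median of 0.74 (percentile 99.4 of machinery lists), with 6 of 28 higher and 3 lower, and a mean of 0.40 (percentile 40.2 of machinery means). The serine synthesis enzyme PHGDH stood at 1.40, whereas ATF4 itself stood at -2.06 (4.17-fold lower), and CEBPB at -1.48. Chaperones of the endoplasmic reticulum had a median of 0.60, with PDIA6 at 1.47, SEL1L at 1.13 and DNAJC3 at 1.08, and heat shock genes 0.63, with HSPA4L at 1.74, CHORDC1 at 1.08 and HSPD1 at 1.03. Both medians lay inside the machinery range. FOXO targets had a median of 0.14, or 0.24 without shared genes, and a mean of 0.071, with SESN3 at 1.48, GADD45B at -2.76 and SESN1 at 0.83. Genes known as p53 targets had a median of 0.15, or 0.35 without shared genes, with RRM2B at 1.46 and XPC at 0.80.

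Metabolic genes had medians of 0.69 for sterol and fatty acid synthesis, 0.65 for the respiratory chain and 0.28 for glycolysis and hypoxia. Sterol synthesis stood at percentile 97.6 of machinery lists, with 4 of 23 members higher, among them SC5D at 1.48, MSMO1 at 1.37 and ACLY at 1.23. In the respiratory chain ATP5F1A stood at 1.36, NDUFS3 at 1.04 and NDUFB9 at 0.86. In glycolysis PGK1 stood at 1.19, P4HA1 at 0.96 and LDHA at 0.91. The glycolysis list was above all genes but at percentile 10.3 of machinery lists, and it was inside the range of all genes by its mean (percentile 95.4) or without shared genes (93.7).

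Lists of markers of other cell types had negative medians. Lymphoid genes had a median of -0.20, with 0 of 18 past 2-fold and CD7, CD3D and CD2 between -0.67 and -0.45. Granulocyte and monocyte genes had a median of -0.22, with CEBPA at -1.07, LYZ at 1.05 and FCN1 at -0.77. Epithelial and stromal genes had a median of -0.23, just below random lists of all genes but inside their range by its mean of -0.096, with EPCAM at 1.25, ACTA2 at 0.83 and COL1A1 at -0.57. All 3 lay inside the range of random silent lists, and by the mean the lymphoid (percentile 0.66) and granulocyte (0.47) lists stood below all genes. Megakaryocyte and platelet genes had a median of -0.17, above random silent lists (percentile 98.26), and a mean of -0.11. In that list 0 of 20 were past 2-fold, with F2R at 0.99, TUBB1 at 0.94 and THBS1 at -0.70. Interferon-stimulated genes had a median of -0.17, also above random silent lists (percentile 98.83), and a mean of -0.039. Of these, 0 of 24 were past 2-fold, with SAMD9 at 0.84, OAS3 at 0.70 and IRF7 at -0.70.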

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

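Every test in this part was chosen after the differences had been seen. Probes outside the gene comparisons also differed between the arrays: 273 of 7807 probes with no gene listed were at least 2-fold lower with EPO against 93 higher, and 150 of 1752 probes with several genes were lower against 30 higher. Among the latter were probes shared by the heat shock genes HSPA1A and HSPA1B, with differences between -0.77 and -1.98.

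The first pattern is that machinery genes were higher and silent families lower with EPO. A constant shift of all log2 values between the arrays is argued against by the gap between the class medians. This gap was 0.79 (95% bootstrap interval over genes 0.71 to 0.86). A weaker or noisier signal on the array without EPO stays open: 3 of the 3 fixed lists of other cell types had a negative median, but all lay inside random silent lists, so they restate the fall of the silent families and decide nothing. This and a response of the cells to EPO cannot be told apart, since there is 1 array per group and neither the intensities nor the other arrays behind the baseline were analysed here.

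The second pattern is that immediate-early genes were lower with EPO. The difference of silent genes between the arrays may account for the list median, which lay at percentile 17.0 of random silent lists. That difference does not account for the list mean of -0.82, which lay below the lowest of 10000 random silent means (-0.61). Which array moved cannot be told from the difference. Stress of the cells without EPO before harvest remains open. The HSPA1A and HSPA1B probes moved with the immediate-early genes. The heat shock list instead had a positive median, at percentile 87.2 of machinery lists, and stood at 97.53 by the mean. Swapped labels of the arrays also remain open: CISH, SOCS2, PIM1 and BCL2L1 had a median of 0.72, at percentile 84.2 of random machinery lists, while ID1 and SOCS1 were lower. Small nuclear RNAs were lower still, with a median of -1.48. A cause on the array that reaches beyond silent genes was therefore not excluded. An effect of EPO itself on these genes stays open and untested.

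The third pattern is that 14 of the 28 lists, though not the cytosolic ribosomal proteins, stood above random lists of all genes. The shift of cellular machinery genes may account for part of it: with list members of that class left out, which leaves too few genes of the respiratory chain, 7 of 13 lists were not above random machinery lists. The housekeeping list was among those above, so a place above machinery genes does not by itself show a response. For mitosis and sterol synthesis the excess held by the mean too, for ATF4 targets, iron uptake and erythroid surface genes it did not, and its source stays open. The arrays correlated at -0.69 across probes, to which centring on a baseline that holds both arrays can contribute. A linear trend of the array with EPO on the array without EPO was then removed. Among random lists of all genes, residuals of ATF4 targets stood at percentile 99.85 (99.9 with a curved, lowess trend) and mitosis at 97.15 (93.7). Iron uptake stood at 2.5 (6), sterol synthesis at 2.1 (7.9) and erythroid surface genes at 1.35 (1.25). Such residuals do not follow the difference between the arrays. C1QTNF9B, at 0.43 with EPO and 0.53 without EPO, ranked 2 by the linear residual, and BCL2L1, with a difference of 1.40, ranked 6498. The residuals also keep the unknown baseline, so they do not show which lists responded to EPO.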

How the results depend on the processing

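Alternatives marked as added were chosen after seeing the data. Under the alternatives written beforehand that could be run, no list that stood apart changed sign. With a class median subtracted (added), 1 of these 17 lists, glycolysis, turned negative against machinery genes, and 2, the epithelial list and the histones, turned positive against silent families. The counts depended on the threshold: 3333 higher and 854 lower genes at 1.5-fold, and 67 and 68 at 3-fold. They also depended on the reference. With the machinery median subtracted, 134 genes were higher and 1085 lower, so most calls were then lower ones. With the silent median subtracted, 2804 were higher and 101 lower. Among protein-coding genes alone (added), 77 were lower. Of the named genes, 24 of 55 higher ones stayed past 2-fold with the machinery median subtracted, and 18 of 20 lower ones with the silent median subtracted (added), without CEBPA and CDKN1C. List values moved by more than the spread of random lists in the following cases. With the mean in place of the median, immediate-early genes stood at -0.82, erythroid surface genes at 0.57, epithelial and stromal genes at -0.096, G1-S genes at 0.63, ATF4 targets at 0.40, interferon genes at -0.039, histones at -0.50 and the housekeeping list at 0.76. Without genes shared between lists, STAT5 targets stood at -0.15 and p53 targets at 0.35. With the probe of smallest difference (added), anti-apoptotic genes stood at 0.43. The cause of these moves was not tested. Of 17 lists outside the range of all genes, glycolysis was lost without shared genes, and with the mean glycolysis and the epithelial list were lost while the granulocyte and lymphoid lists were gained. Against random lists of protein-coding genes (added), 18 lists stood apart. Against random machinery lists (added) 17 did, but 5 above and 12 below in place of 14 and 3, and 9 of the 14 were no longer above. By the mean (added), 5 stood above machinery lists, but 2 of these were among the 5 by the median. The filters on dim genes, lowess on level, matched random lists, quantile normalization and brightest-probe rule were not run, because the table holds no levels. No paired analysis was possible because each group has 1 array. Without levels, genes near background could not be told from expressed genes.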

Other observations

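The hypothesis and its tests in this part were chosen after the data had been seen. A hypothesis is that EPO raised STAT5 targets in imatinib-treated cells. It was tested on the plain difference, in which the median of the fixed STAT5 list stood at percentile 64.4 of random lists of all genes, inside their central 95%. Members went both ways, from CCND2 at 1.56 to ID1 at -2.97, with CISH at 0.22 and DUSP10 at 0.055. The same median lay at percentile 0.12 of random machinery lists, and the list's mean, -0.12, at 4.63 of random lists of all genes. These values do not favour the hypothesis, and with members going both ways they do not exclude it. Residuals from the linear trend between the arrays were counted as well. Of 20 members, 6 lay in the top 2.5% of genes and 1 in the bottom 2.5%, against 0.5 expected in each. With a curved (lowess) trend, 7 and 0 did. The 7 included SOCS1, which was 5.76-fold lower with EPO, and ID1, 7.84-fold lower, left the bottom 2.5%. The list's median stood at percentile 92.85, or 100 with the curved trend. MYC targets reached 100 and 99.95, and the 479 genes of silent families reached 100 with either trend. A high residual is not a rise with EPO, as SOCS1 shows, and both top counts also included DUSP10, at 0.055. The counts therefore cannot decide the hypothesis. Residuals also keep the unknown baseline, so the hypothesis stays open with 1 array per group.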
